A study of Danio rerio with 4 samples.

How the data were processed

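Cells came from the kidney of adult zebrafish, the organ in which this fish makes its blood. Per the labels, cells with low forward scatter and low side scatter, the lymphoid gate of a flow cytometer, were separated by their Hoechst fluorescence into a side population, called zSP here, and a main population, called zMP. Hoechst is a DNA dye that some cells pump out through membrane transporters, so that the side population is the dimly stained part of the profile. Per the labels' protocols, 20 fish supplied 3 sorting experiments, the lysates were combined within each population, and every pooled RNA was then divided between 2 arrays. The RNA went through 2 rounds of in vitro transcription, which shortens the copies towards the 3′ end, and was labelled with biotin. The arrays of a population therefore repeat the amplification, labelling and hybridization of the same RNA, and each population is represented by 1 pool.

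The authors deposited log2 expression values for 15617 probe sets of an Affymetrix zebrafish array, made with RMA in the affy package per the submitters' processing notes. RMA corrects the background, equalizes the distributions of the probes between arrays and summarises the probes of a set on the log2 scale. The versions, settings and probe set definitions are not given in the sources used here. The values carry no detection calls and no genome coordinates, so none are printed. All 4 deposited columns matched a labelled sample and were used, and the values were taken as deposited. With 115 control probe sets left out, 15502 probe sets remained. The precision is limited by the number of arrays, 2 per population, and by the absence of a biological repeat.

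Among these probe sets, 10795 carried 1 gene in the platform's annotation, 135 carried several and 4572 carried none. No gene was named from a probe set with several. Symbols were updated through their gene identifiers in the gene table of the GRCz12tu assembly, where 8723 of 8796 identifiers were found. The table was used for names alone. A gene was represented by the probe set with the highest mean over the 4 arrays among those annotated to that gene alone, which gave 8793 genes.

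The choices that follow were made before the data were examined, unless stated otherwise. The difference of a probe set is the mean of the zSP arrays minus the mean of the zMP arrays on the log2 scale. Since each population is 1 pool, no test between the populations is possible, and a rule of size took its place. A probe set or gene was called when all 4 differences between a zSP and a zMP array were at least 1, that is 2-fold, in the same direction. The lowest and highest of these 4 differences are the technical error given with each value. No p-value stands behind a call.

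The genes named are the 12 called genes with the largest difference in each direction, clone and locus names left out, and from each gene list the called members with the largest absolute difference, up to 4, or the 2 largest where none was called. The ABC transporters abcg2a to abcg2d and abcb4, and runx1, myb, lmo2, tal1, gata2a and gata2b, were to be named whenever measured. Any other gene was picked after its values were seen, as the text says where it stands. In all, 26 lists of genes were fixed, covering transporters, stem cell regulators, signalling pathways, blood lineages, non-blood cell types, stress, metabolism and housekeeping. Of their symbols, 447 were found directly and 17 under an older symbol, while 279 had no probe set of their own here. A list was described by the median difference of its members, by the number called, and by the percentile of that median among 10000 random lists of the same size matched on mean level in 20 bins. A percentile above 97.5 or under 2.5 describes these pools and is not a test between populations. The error given with a list median is the range of the medians from the 4 pairs of arrays, which need not enclose the median of the mean differences.

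The blank range was set from 49 control probe sets for bacterial genes, artificial tag sequences and fluorescent reporter or recombinase-site sequences, which zebrafish cells do not transcribe. Whether the bacterial controls had been added to the RNA is not given in the sources used here, and none of their group means passed that of the EGFP reporter probe set. A value at or below their highest group mean, 6.15, does not show that a transcript was present. This range was chosen after the controls were seen. Without the EGFP probe set its top would be 5.24.

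Alternatives were other sizes, the difference of means alone, each array left out, median centring, a second quantile normalization, a filter on low values, no shared-sequence probe sets, other ways to combine the probe sets of a gene, and limma 3.58.1 in R 4.3.3 over the 4 arrays. The limma fit, run plainly, with a trend on mean level and with the replicate number as a block, compares the 2 RNA pools against the spread between aliquots, not the populations. Gene lists were also put through limma's camera with a preset inter-gene correlation of 0.01 and with an estimated one, with Benjamini-Hochberg adjustment over the 26 lists. With an estimated correlation, camera relies on the few residual degrees of freedom of the 4 arrays, which limits how low its p values can be. Cyclic loess and a filter to probe sets above the blank range were added after the data were seen, as were 10 symbol families used in the closing observations and a list of leukocyte genes. The filter asks that the mean of either pool lies above the range, so that it favours members with a large difference. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 did the remaining work.

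The calling was tested on simulated data for the 15502 probe sets with the real mean levels, in which 200 probe sets were changed. The noise was normal, with the aliquot spread averaged over probe sets of similar level, and the simulated pools had no common offset. The rule of size called 52.0% of probe sets changed by 1.5, 76.0% of those changed by 2.0, 96.0% of those changed by 3.0 and 100.0% of those changed by 4.0 on the log2 scale. It called 137 of 15302 unchanged probe sets, or 0.90%, a share that leaves out any common offset between the real pools. At an adjusted p under 0.05, limma called none of the changes of 1.5 and 2.0, 20.0% of those of 3.0 and 66.0% of those of 4.0, and none of the unchanged probe sets.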

Results

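Gene expression was measured in 2 populations of adult zebrafish kidney cells on 4 arrays, 2 for the zSP pool and 2 for the zMP pool. The comparison asks which transcripts set cells of the Hoechst side population apart from the other cells of the lymphoid gate. In blood-forming tissue such a profile is used to enrich for stem cells. Every value below comes from 1 RNA pool per population, so that the spread between arrays is technical and differences have no biological replicate check. Differences are zSP minus zMP on the log2 scale, and the range after a difference spans the 4 pairs of arrays.

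The 2 aliquots of a pool resembled each other more than the pools did. Pearson's r across the 15502 probe sets, which are not independent replicates, was 0.943 between the zSP arrays and 0.952 between the zMP arrays, against a mean of 0.871 between arrays of different pools. The SD of the difference between arrays was 0.76 for zSP, 0.67 for zMP and 1.12 on average between pools. The array medians lay between 4.05 and 4.15, and 20.3% to 23.5% of the probe sets of an array lay above the blank range. The control probe sets differed between the pools. The 49 blank control probe sets had a median difference of -0.38, with 48 of them lower in zSP. The 3′ minus 5′ difference of the GAPDH control probe sets was 3.94 in zSP and 3.09 in zMP, a difference of 0.86 for this transcript. The median difference of all probe sets was -0.21, and -0.01 after cyclic loess.

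Of 8793 genes, 690 were called higher in zSP and 254 higher in zMP, so that 73.1% of the called genes were higher in zSP. That share was 54.5% at a size of 1.5-fold, 60.6% by the difference of means alone, 62.3% to 66.2% with 1 array left out, 86.7% at 3-fold and 83.1% after cyclic loess, the last with 856 of the 944 called genes keeping their call. Differences of 8-fold and more were found among 201 called genes towards zSP and 17 towards zMP. Of the 690 genes higher in zSP, 495 had a zSP mean above the blank range, and 561 had a zMP mean within it, so that their difference stands against background fluorescence. The EGFP control alone set the top of that range at 6.15, and with the next control, at 5.24, these counts were 598 and 479. Of the 254 genes higher in zMP, 192 had a zMP mean above the range up to 6.15, and 129 had a zSP mean within it. Among probe sets, 1031 were called higher in zSP and 387 higher in zMP, together 9.15% of those tested. Between the RNA pools, limma with Benjamini-Hochberg adjustment passed 268 and 42 of these genes, all of them called by size too. With 1 array left out only 2 pairs need to pass, and the genes higher in zSP then numbered 1044 without zSP replicate 1 and 1092 without zSP replicate 2. The genes higher in zMP numbered 588 and 557 without zSP replicates 1 and 2, and 589 and 532 without zMP replicates 1 and 2.

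Epithelial genes headed the zSP side. The epithelial adhesion molecule epcam had the largest difference of the named genes, 7.65 (7.47 to 7.83), with a zSP mean of 11.57 against 3.92 in zMP. Its second probe set was not called, and the mean over both was 4.56. The simple-epithelial keratin krt18a.1 followed at 6.71 (6.38 to 7.03). The tight-junction claudins cldn3d, cldnb and cldn3c stood at 6.62, 6.05 and 6.04. The epithelial transcription factor elf3 was higher by 6.12, the hemidesmosome-associated lad1 by 6.05 and the tetraspan membrane protein tm4sf4 by 6.45. The actin-binding genes tagln, a smooth muscle marker, and cfl1l, a cofilin relative, were higher by 6.47 and 6.53. The chitinase chia.6 at 6.63 and the adaptor hsh2d at 6.52 completed the 12. All 12 had zMP means within the blank range.

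**Figure D1:**
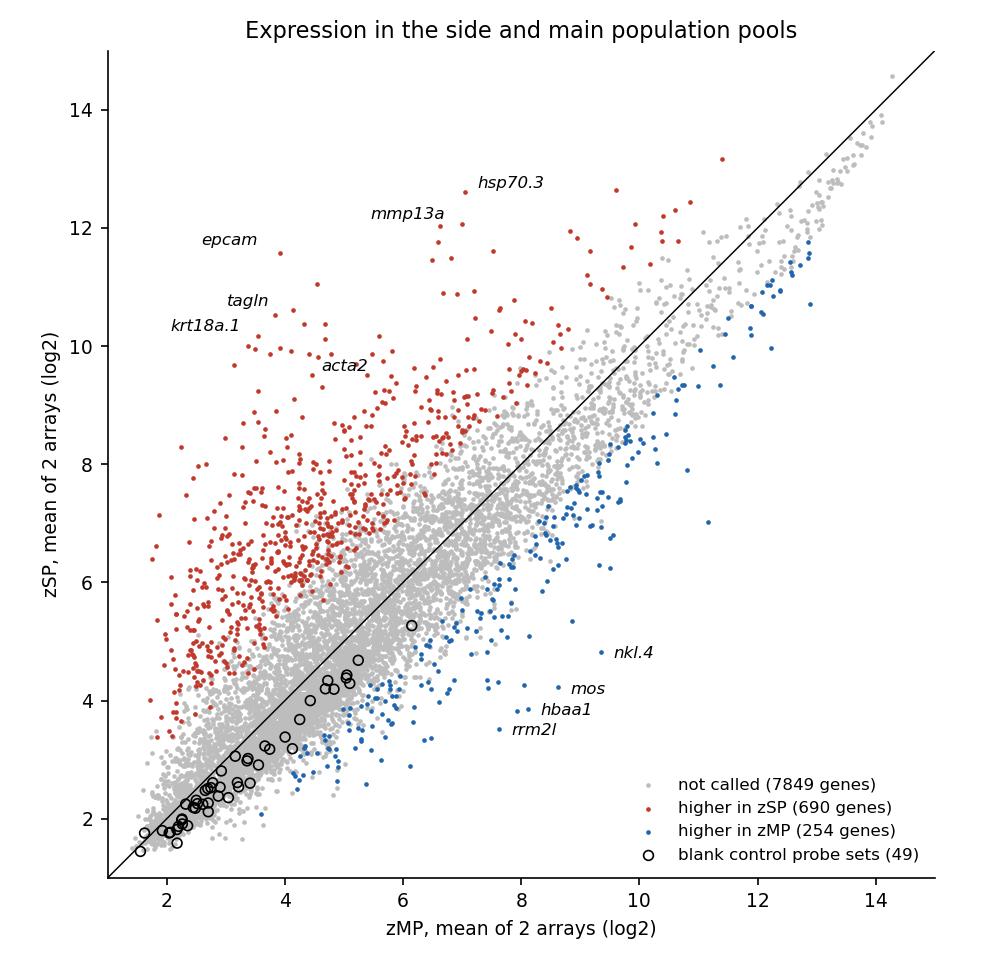
Mean log2 value of each gene in zMP (x axis, 2 arrays) and zSP (y axis, 2 arrays), with genes called higher in zSP in red, genes called higher in zMP in blue, the rest in grey and the 49 blank control probe sets as circles. The 690 red genes reach differences of 6 and more, while the largest difference among the named blue genes is -4.53, and the blank controls lie just under the diagonal.

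Among the 12 named genes with the largest differences towards zMP, the cytotoxic lymphocyte peptide nkl.4 differed by -4.53 (-5.74 to -3.32), the adult globin hbaa1 by -4.24 (-4.52 to -3.97) and the ribonucleotide reductase relative rrm2l by -4.09 (-4.16 to -4.02). The meiotic kinase mos differed by -4.41 (-5.66 to -3.15). The inflammasome adaptor pycard stood at -4.10 with a wide range (-5.81 to -2.38). The ribosomal oxygenase riox2 differed by -3.78, the kinase relative camkvl by -3.51 (-1.86 with its probe sets averaged), the heme A synthesis gene cox15 by -3.29, the ribosome biogenesis gene bxdc2 by -3.22 and dtwd1 by -3.10. The membrane protein gene tmem256 at -3.26 (-4.92 to -1.59) and the carboxypeptidase cpm at -3.04 (-4.27 to -1.81) rested partly on single arrays. Without zSP replicate 2 the difference of tmem256 was -1.81, and that of cpm was -1.81 without zSP replicate 1 and -1.87 with its probe sets averaged. Apart from tmem256, all 12 had zSP means within the blank range, so that their differences and order stand against background.

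Regulators of blood stem and progenitor cells did not move as a group, but only 14 of the 30 had a mean above the blank range in either pool. For the others it was not shown that a transcript was present. Over these 14, a selection that favours large differences, the median lay at the 63.9th percentile of matched random lists. Of 30 members measured, 4 were called higher in zSP and none higher in zMP, with a list median of -0.24 (-0.31 to -0.06) at the 44.2th percentile of matched random lists, which was -0.12 at the 68.1th without zMP replicate 2, 0.05 after cyclic loess and 0.33 above the blank range. The homeobox gene meis1b was higher by 2.35 (1.31 to 3.39), the zinc finger gene gata2a by 2.06 (1.78 to 2.34), the immediate early gene egr1 by 1.95 (1.85 to 2.05) and the Polycomb gene bmi1b by 1.33 (1.01 to 1.64). The egr1 call ended at 0.75 when its probe sets were averaged, and the bmi1b call ended at 1.09 after a second quantile normalization. Other core regulators were not called. The differences were -0.29 (-0.51 to -0.07) for runx1, -0.39 (-0.73 to -0.04) for myb, -0.70 (-0.77 to -0.63) for lmo2 and 0.23 for tal1. Those of runx1 and tal1 were -0.01 and 0.41 after cyclic loess. Leaving out zMP replicates 1 and 2 in turn gave -0.70 and -0.077 for myb, and leaving out zSP replicate 1 or zMP replicate 2 gave -0.17 and -0.19 for runx1. The means of runx1 and tal1 lay within the blank range in both pools. The zMP means of meis1b, gata2a and bmi1b lay within it too, so that their differences stand against background. No probe set of its own was annotated to gata2b.

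The transporters linked to Hoechst efflux, abcg2a, abcg2b, abcg2c, abcg2d and abcb4, had no probe set of their own in the annotation and were not analysed here. Of 5 other ABC transporter genes measured, abcc3, an organic anion exporter, was called higher in zSP by 2.02 (1.40 to 2.63), with both means within the blank range. The list median was 0.13 (0.07 to 0.20), at the 75th percentile, which was -0.052 without zMP replicate 1.

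Markers of non-blood cells were among the genes called higher in zSP. In the kidney tubule and epithelium list, 12 of 28 members were called higher in zSP and none higher in zMP, led by epcam, krt18a.1, cldnb and cldn3c. The list median was 1.33, above all 10000 random lists, and 0.59 without zSP replicate 1, with a highest value of 1.48 among the 4 pairs of arrays. Between the RNA pools, limma's camera gave this list an adjusted p of 1.5e-06 with the preset correlation and 0.26 with an estimated one. Picked after their values were seen, the kidney tubule genes slc13a1, a sulfate transporter, cdh17, a cadherin of the tubule, and hnf1bb, a tubule transcription factor, were higher by 3.31, 4.11 and 3.24, while slc12a3 and pax8 stood at -0.93 and -0.78 and were not called. Of these 5, all but cdh17 had both means within the blank range. In the stroma and mesenchyme list, 10 of 16 members were called higher in zSP, with a median of 2.17 (2.19 to 2.24), also above all the random lists, and adjusted p values in camera of 1e-06 and 0.27. The smooth muscle genes tagln and acta2 were higher by 6.47 and 5.46, the matrix gene postnb, with both means within the blank range, by 3.71 (1.82 with its probe sets averaged, 1 of which has the other sign) and the secreted factor ccn2a by 3.70. In either pool, 8 of the 28 epithelial and 9 of the 16 stroma members had a mean above the blank range. Both list medians therefore include members whose transcripts were not shown to be present. Only 1 member of the epithelial list and none of the stroma list had a zMP mean above the blank range. In the endothelium list, 3 of 14 members were called higher in zSP, the VEGF receptor kdrl by 2.64 (1.51 to 3.76) with both means within the blank range, the caveolin cav1 by 2.63 (1.13 to 4.14) and the flow-responsive factor klf2a by 1.96. The cav1 call ended at 0.66 when its probe sets were averaged and at 0.50 without shared-sequence probe sets. The endothelial list median, 0.35 (0.05 to 0.65) at the 97.7th percentile, was 0.63 at the 99.3th percentile without zSP replicate 1, 0.07 at the 88.5th without zSP replicate 2 and 0.20 at the 92.3th without zMP replicate 1. Its adjusted p in camera was 0.097 with the preset and 0.52 with the estimated correlation. On the same arrays 18 leukocyte genes, listed after the data were seen, had a median of -0.64, and the GAPDH 3′ minus 5′ difference was larger in zSP by 0.86.

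**Figure D2:**
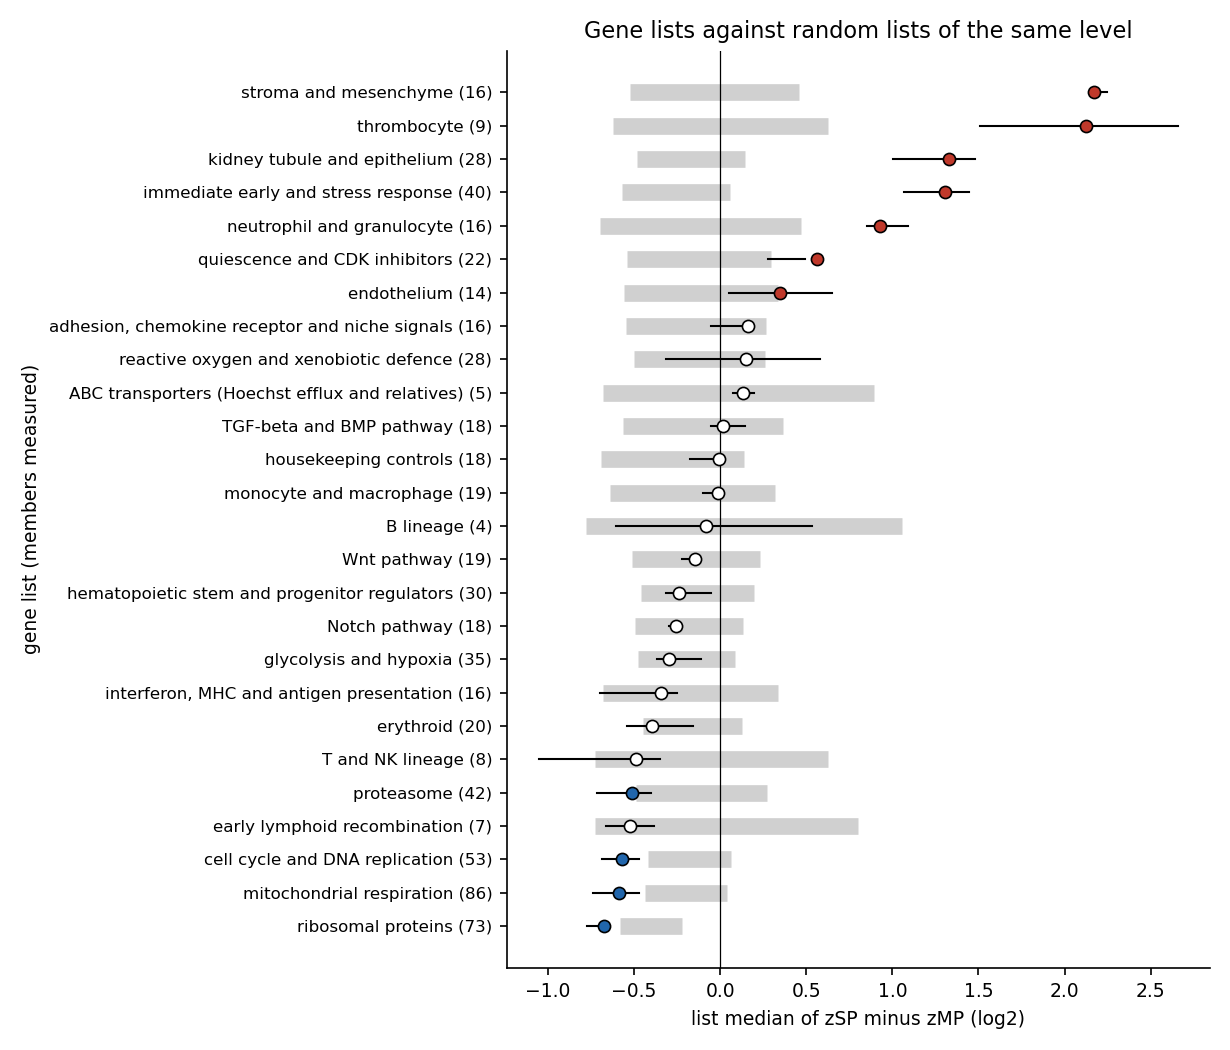
Median zSP minus zMP difference (log2, x axis) of each of the 26 gene lists (y axis, members measured in parentheses), with grey bars for the middle 95% of 10000 random lists matched on mean level and black lines for the range of the medians from the 4 pairs of arrays. Lists in the top 2.5% of their random lists are red, from stroma and mesenchyme at 2.17 to endothelium at 0.35, and lists in the bottom 2.5% are blue, from proteasome at -0.51 to ribosomal proteins at -0.67.

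Many immediate early and stress genes were called higher in zSP, 20 of 40 members, and none higher in zMP. The median was 1.31 (1.07 to 1.45), again above all the random lists. Between the RNA pools, limma's camera gave the list an adjusted p of 2.7e-12 with the preset correlation and 0.26 with an estimated one, and the GAPDH 3′ minus 5′ difference was larger in zSP by 0.86. The heat shock genes hsp70.3 and hsp90aa1.2 were higher by 5.55 (5.41 to 5.69) and 4.23, the stress transcription factor atf3 by 4.96 (4.76 to 5.16) and the cytokine signalling inhibitor socs3b by 4.12. The only probe set of hsp70.3 shares sequence with other transcripts. In this list 29 members had a zMP mean above the blank range. In the list of quiescence genes and CDK inhibitors, 4 of 22 members were called higher in zSP, klf2a by 1.96, the antiproliferative tob1a by 1.91, klf6a by 1.74 and the glucocorticoid-induced tsc22d3 by 1.15. No CDK inhibitor was among the called members. The median was 0.56 at the 99.8th percentile, with 0.28 to 0.49 for the single pairs of arrays, and 0.37 without zSP replicate 1, and the adjusted p in camera was 0.0084 with the preset and 0.27 with the estimated correlation. The call of tsc22d3 ended at 0.95 after a second quantile normalization. On the same arrays the blank controls had a median difference of -0.38.

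Myeloid markers went both ways. In the neutrophil and granulocyte list, 7 of 16 members were called higher in zSP and 1 higher in zMP, with a median of 0.93 (0.85 to 1.09) at the 99.8th percentile. In limma's camera between the RNA pools the list had an adjusted p of 0.0043 with the preset correlation and 0.27 with an estimated one. The matrix metalloproteinases mmp9 and mmp13a, which other cells can make too, were higher by 5.25 (4.35 to 6.15) and 5.07 (4.35 to 5.79), the transcription factor cebpd by 3.57 (1.84 with its probe sets averaged) and the metalloproteinase inhibitor timp2b, with both means within the blank range, by 2.80. When the probe sets of a gene were averaged the list median was 0.64. Picked after their values were seen, the neutrophil peroxidase mpx was higher by 2.05 (0.51 and not called with its probe sets averaged), the oxidase subunit ncf4, the member higher in zMP and within the blank range in both pools, differed by -1.33 (-1.07 and not called after cyclic loess) and the lysozyme gene lyz by -0.40. In the monocyte and macrophage list, 5 of 19 members were called higher in zSP and 2 higher in zMP, with a median of -0.01 at the 83.4th percentile and a mean of 0.44. This median was 0.16 after cyclic loess and -0.17 at the 61.2th percentile with the probe sets of a gene averaged. The lysosomal protease lgmn was higher by 3.40, the lipid carrier apoeb by 2.94, the amino acid transporter slc7a7, with both means within the blank range, by 2.90 and the granulin grna.1 by 2.77. The scavenger receptor marco was higher by 1.60, and the members higher in zMP were the actin regulator coro1a at -2.02 and cd74b at -1.17, where marco and coro1a were picked after their values were seen. The call of coro1a ended at -1.09 when its probe sets were averaged. In the thrombocyte list, 4 of 9 members were called higher in zSP, the coagulation factor f13a1a.1 by 2.75 and the extracellular glycoprotein genes thbs1b, fn1b and mmrn2a by 2.60, 2.56 and 2.25. Of these, f13a1a.1, thbs1b and mmrn2a had both means within the blank range, which does not show that their transcripts were present. The list median was 2.12 (1.51 to 2.66) at the 100th percentile when rounded, and 1.27 without zSP replicate 1, with adjusted p values in camera of 0.0013 and 0.27, while the thrombocyte integrin itga2b, picked after its values were seen, differed by 0.17. On the same arrays the stroma and epithelial medians were 2.17 and 1.33, the leukocyte genes had a median of -0.64, and the GAPDH 3′ minus 5′ difference was larger in zSP by 0.86.

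Lymphoid and erythroid lists lay within the middle 95% of random lists with all arrays and genes, and their called members were mostly higher in zMP. Of 8 T and NK genes, nkl.4 and the costimulatory receptor cd28, -1.45 (-1.56 to -1.35) with both means within the blank range, were called higher in zMP, and the list median was -0.49 at the 19.1th percentile. It was -0.37 at the 39.3th without zSP replicate 1, -0.83 at the 2.03th without zSP replicate 2 and -0.80 at the 0.76th with the probe sets of a gene averaged. Over the 3 members above the blank range in either pool, a selection that favours large differences, it was -1.99 at the 0.09th. None of 4 B lineage genes was called, with blnk at -0.88 and btk at 0.72 and a median of -0.08 (-0.60 to 0.53) at the 53.9th percentile. This median was 0.38 without zSP replicate 1, -0.50 without zSP replicate 2, 0.07 without zMP replicate 1 and 0.10 after cyclic loess. Of the 4 genes only btk had a mean above the blank range, and both means of blnk lay within it. None of 7 early lymphoid recombination genes was called, with ikzf1 at -1.85 (-2.99 to -0.71) and tcf12 at -1.36 (-2.15 to -0.57) and a median of -0.52 at the 15.5th percentile. The ikzf1 difference was -1.17 without zMP replicate 2, and that of tcf12 was -0.75 without zSP replicate 2. No early lymphoid member had a mean above the blank range, and the list median was -0.26 after cyclic loess. Of 20 erythroid genes, hbaa1 and the peroxiredoxin prdx2, -1.17, were called higher in zMP and the carbonic anhydrase ca2, 2.45, higher in zSP, with a median of -0.40 at the 6.52th percentile, which was -0.25 at the 39.97th without zMP replicate 1, -0.51 at the 1.26th without zMP replicate 2 and -0.80 at the 0.55th with the lowest 40% of probe sets left out. The prdx2 call ended at -1.10 after median centring and at -0.92 after cyclic loess, and that of ca2 at 0.88 when its probe sets were averaged. In the interferon, MHC and antigen presentation list, the immunoproteasome gene psmb9a at -1.91, the ubiquitin-like isg15 at -1.55 and the invariant chain cd74b at -1.17 were called higher in zMP and irf1b at 1.31 higher in zSP, among 16 members with a median of -0.34 at the 38.9th percentile, which was -0.54 without zSP replicate 2. The cd74b call ended at -1.09 after median centring, -0.92 after a second quantile normalization and -0.74 after cyclic loess.

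**Figure D3:**
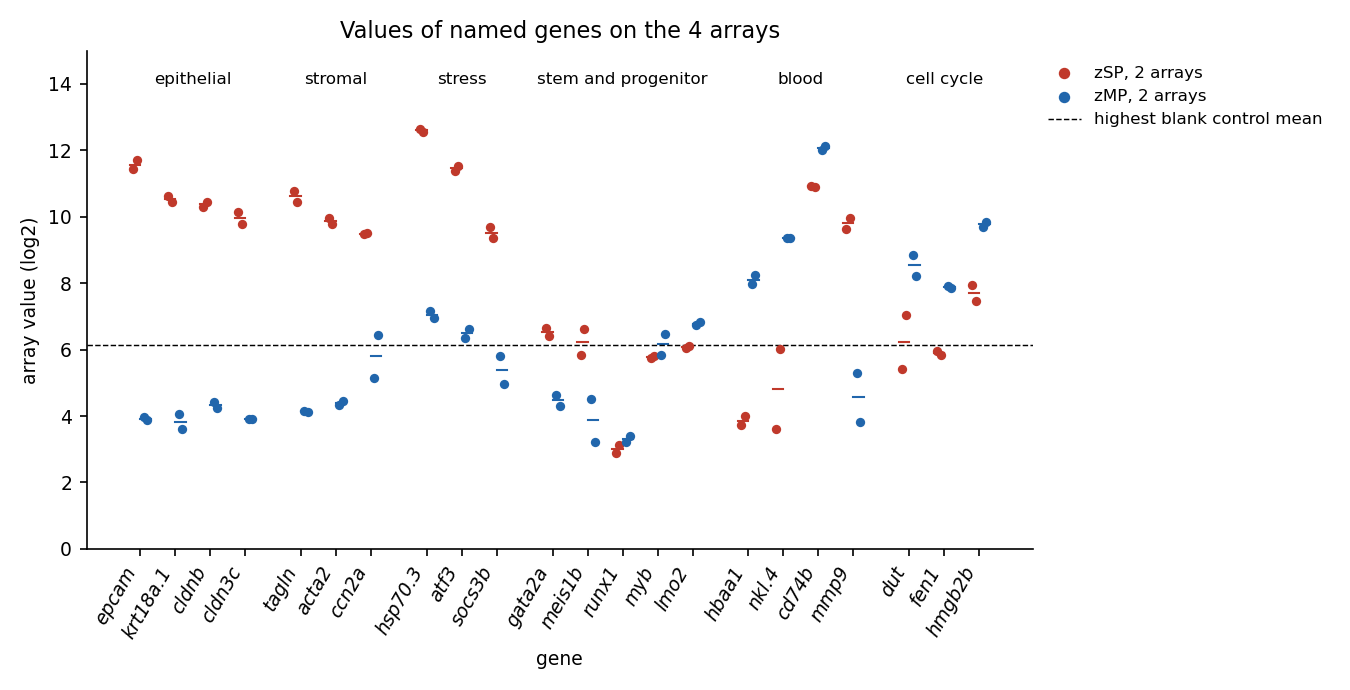
Log2 value (y axis) of named genes (x axis) on each of the 2 zSP arrays (red points) and 2 zMP arrays (blue points), with short lines for the pool means and a dashed line at 6.15, the highest mean of a blank control. Epithelial, stromal and stress genes are separated by more than the spread between aliquots, runx1 lies under the dashed line in both pools, and dut and nkl.4 differ visibly between the 2 zSP arrays.

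In the lists of growth and division a minority of members was called, all of them higher in zMP. In the cell cycle and DNA replication list, 7 of 53 members were called higher in zMP and none higher in zSP, with a median of -0.57 (-0.69 to -0.47), under all the random lists. Only 17 of the 53 had a mean above the blank range in either pool. For this list limma's camera between the RNA pools gave an adjusted p of 3e-05 with the preset correlation and 0.26 with an estimated one. The nucleotide hydrolase dut differed by -2.30 (-3.45 to -1.16), and by -1.48 without zSP replicate 1. The chromatin protein hmgb2b differed by -2.07 (-2.39 to -1.75), the replication nuclease fen1 by -2.00 (-2.08 to -1.91) and the condensin subunit smc4, with both means within the blank range, by -1.74. After cyclic loess 4 of the 53 members were called higher in zMP. Of 73 ribosomal protein genes, 15 were called higher in zMP and none higher in zSP, led by rpl22l1 at -1.76, rpl39 at -1.56, rps24 at -1.45 and rpl17 at -1.43. Their median was -0.67 (-0.77 to -0.70) at the 0.06th percentile, and the adjusted p in camera was 1.2e-11 with the preset and 0.45 with the estimated correlation. This result depended on the scaling, since the median was -0.26 at the 26.5th percentile after a second quantile normalization and -0.18 at the 4.42th after cyclic loess, which also ended 14 of the 15 calls, all but that of rpl22l1. In mitochondrial respiration, 5 of 86 members were called higher in zMP and none higher in zSP, with a median of -0.59 (-0.74 to -0.47) at the 0.03th percentile and adjusted p values of 0.00089 and 0.27 in camera. The largest were the ATP synthase subunit atp5pd at -1.97, the assembly factor sdhaf4 at -1.60, the oxidase subunit cox7b at -1.53 and the ATP synthase subunit atp5l at -1.12, and the oxidase subunit cox6b2, picked after its values were seen, stood at -1.09. The calls of cox7b, atp5l and cox6b2 ended at -1.22, -0.80 and -0.73 after cyclic loess, and that of atp5l at -0.60 with its probe sets averaged. In the proteasome list, 2 of 42 members, psmb9a at -1.91 and psmd3 at -1.61, were called higher in zMP, with a median of -0.51 at the 1.80th percentile and adjusted p values of 0.097 and 0.48 in camera. The proteasome median was -0.30 at the 14.3th percentile without zMP replicate 1. It was -0.44 at the 5.85th without zSP replicate 2 and -0.32 at the 2.69th after cyclic loess. The psmd3 call ended after median centring and cyclic loess, where its difference was nearly as large at -1.53 and -1.52. Beside these values, the blank controls had a median of -0.38, the 18 leukocyte genes one of -0.64 and all genes together one of -0.20, and the GAPDH 3′ minus 5′ difference was larger in zSP by 0.86.

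Signalling and metabolic lists lay within the middle 95% of random lists with all arrays and genes, and some left it under an alternative. No Notch gene of 18 was called, with jag1a at 1.68 (0.07 to 3.29) and dla at -0.99, and a median of -0.26 at the 46.3th percentile. Both means of jag1a and of dla lay within the blank range, and only 4 of the 18 members had a mean above it in either pool. The jag1a difference was 3.23 without zSP replicate 1 and 0.14 without zSP replicate 2. Of 19 Wnt genes, the receptor fzd7b was called higher in zSP by 3.29 (2.77 to 3.80), and by 2.08 with its probe sets averaged. The Wnt list median was -0.15 at the 69.2th percentile, 0.10 after cyclic loess and 0.97 over the 3 members above the blank range. Of 18 TGF-beta and BMP genes, 3 were called higher in zSP, the BMP-responsive inhibitors id1 by 3.48 (3.29 to 3.67) and id2b by 2.52 and the receptor bmpr1aa by 3.09, with a median of 0.02 at the 81.5th percentile. The bmpr1aa call ended at 1.17 when its probe sets were averaged. The list median was 0.26 without zSP replicate 1 and -0.061 without zSP replicate 2. Over the 7 members above the blank range in either pool, a selection that favours large differences, it was 1.65 at the 99.4th percentile. In the adhesion and niche list, the tetraspanin cd9b was higher in zSP by 5.71 (5.45 to 5.97) and the chemokine cxcl12a by 3.18 (2.01 with its probe sets averaged). The junction molecule jam2a differed by -1.91. The 16 members had a median of 0.16 at the 94.9th percentile, which was 0.02 at the 89.4th without zSP replicate 2. It was 0.31 at the 98.3th after a second quantile normalization and -0.06 over the members above the blank range. In the reactive oxygen and xenobiotic list, 5 of 28 members were called higher in zSP and 3 higher in zMP. The glutathione peroxidases gpx1b and gpx4a were higher by 5.09 and 2.19, the thioredoxin txnb by 2.69 and the glutathione synthesis gene gclc by 1.96. Picked after their values were seen, the peroxiredoxin prdx1 was higher by 1.39, and gpx1a at -1.76, the mitochondrial dismutase sod2 at -1.29 and prdx2 were the members higher in zMP. The call of sod2 ended at -1.10 after cyclic loess and that of prdx1 with its probe sets averaged. This median, 0.15 (-0.32 to 0.58) at the 93.4th percentile, was -0.11 at the 68.7th without zSP replicate 2 and 0.01 at the 73.9th without zMP replicate 2, and it entered the top 2.5% of random lists without zSP replicate 1 and without zMP replicate 1, at the 99.7th and 99.6th percentiles. In glycolysis and hypoxia, eno1b, gapdh and the hypoxia factor hif1ab were called higher in zSP by 2.27, 1.85 and 1.64 and ldha and, picked after its values were seen, ldhba were called higher in zMP at -1.45 and -1.36, among 35 members with a median of -0.30 at the 31.4th percentile, which was -0.085 at the 75.9th without zMP replicate 2. The zMP mean of this gapdh probe set, 4.79, lay within the blank range, and the GAPDH control probe sets, at higher levels, differed by 0.23 at the 3′ end, 0.16 in the middle and -0.62 at the 5′ end. The eno1b difference was 1.35 without zSP replicate 1, and the ldhba call ended at -1.11 after cyclic loess. Of 18 housekeeping genes, gapdh with the same reservation, ubb, actb1 and tuba1b were called higher in zSP by 1.85, 1.82, 1.78 and 1.40. The median was -0.01 at the 92.8th percentile, 0.20 after a second quantile normalization, 0.29 after cyclic loess and -0.04 at the 97.7th over the 15 members above the blank range. The ribosomal protein gene rps18, picked after its values were seen, was called higher in zMP at -1.21, a call that ended at -0.80 after cyclic loess.

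Over the 26 lists, 7 medians lay in the top 2.5% of random lists and 4 in the bottom 2.5%. Between the RNA pools, limma's camera with the preset correlation passed 9 lists, and none with an estimated correlation, where the lowest adjusted p was 0.26 and 4 lists had an unadjusted p under 0.05. Median and mean differed in sign for the stem cell list (-0.24 and 0.07), the Wnt list (-0.15 and 0.02), the glycolysis list (-0.30 and 0.04), the monocyte list and the housekeeping list, whose mean was 0.07. Camera's direction is relative to the other genes, and the median of all genes was -0.20, so that it need not match the sign of a list. It followed the mean in the stem cell, monocyte and housekeeping lists and the median in the Wnt and glycolysis lists. It was upward for the B lineage list, whose median and mean were both -0.08 and so above that of all genes.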

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

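Results flagged for a closer look

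The 3 values in this part come from control probe sets outside the comparison, and they were chosen after the controls were seen. A signal appeared in the control probe set for the EGFP reporter, whose mean on the zMP arrays was 6.15, against 5.27 on the zSP arrays and 5.24 for the next highest blank control in zMP. This probe set alone sets the top of the blank range. Under 5.24 the higher means of timp2b, postnb, kdrl, smc4, ikzf1, tcf12, hnf1bb, slc13a1, col1a2 and eif2b1 would lie above that range, and that of slc7a7 at its edge. The 49 blank controls differed by a median of -0.38 between zSP and zMP, with 48 of them lower in zSP and none called. The GAPDH control probe sets for the 3′ and the 5′ end of the transcript differed by 0.86 more in zSP than in zMP, at 3.94 against 3.09. No cause of these 3 values was tested, and what a difference in background would do to the gene lists is given with the other observations.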

How the results depend on the processing

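How the results depend on the processing

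Cyclic loess and the filter to probe sets above the blank range were chosen after seeing the data, and the other alternatives were fixed before. That filter passes a probe set through either pool, so that medians above the blank range are partly selected for large differences. No called value changed sign under any alternative run. For the values that follow the cause was not tested, except where fewer pairs of arrays, another size or fewer probe sets make a count larger or smaller by construction.

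The main counts were 1031 probe sets and 690 genes higher in zSP, and 387 probe sets and 254 genes higher in zMP. A size of 3-fold gave 593 and 396 towards zSP and 94 and 61 towards zMP. A size of 1.5-fold gave 1530 probe sets and 1017 genes towards zSP and 1337 and 849 towards zMP, and the difference of means alone gave 1878 and 1245 towards zSP and 1189 and 811 towards zMP. Leaving out each array in turn, where 2 pairs have to pass in place of 4, gave 1443 to 1680 probe sets and 975 to 1092 genes towards zSP and 818 to 905 probe sets and 532 to 589 genes towards zMP. All 1418 called probe sets kept their call by construction. Cyclic loess gave 250 probe sets and 166 genes towards zMP. Median centring, a second quantile normalization, the filters and other ways to combine probe sets left all 4 counts within 1.5 times the main ones, the furthest being the 688 probe sets towards zSP above the blank range.

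Between the RNA pools, limma at an adjusted p under 0.05, with or without a 2-fold size, passed 380 probe sets and 268 genes towards zSP and 70 and 42 towards zMP. With a trend on mean level it passed 449 and 331 towards zSP and 176 and 145 towards zMP. With the replicate number as a block, the replicate block of limma passed 0 probe sets and 0 genes in both directions, against 3305 probe sets and 1865 genes at an unadjusted p under 0.05. That fit spends degrees of freedom on a number that does not pair the aliquots, whose deviations from their pool means had a correlation of -0.011 between zSP and zMP.

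With the lowest 40% of probe sets left out, Pearson's r was 0.905 between the zSP arrays, 0.919 between the zMP arrays and 0.769 between the pools, and the SD of the differences was 0.86, 0.80 and 1.34. As to signal over background, 2921 of 8793 genes had a higher mean above the blank range, and 4057 with the EGFP control left out of that range.

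With each array left out in turn, list medians ranged from -0.052 to 0.19 for ABC transporters, -0.29 to -0.26 for Notch, -0.22 to -0.15 for Wnt, -0.061 to 0.26 for TGF-beta and BMP, -0.83 to -0.33 for T and NK, -0.50 to 0.38 for B lineage, -0.28 to -0.12 for stem cell regulators, -0.51 to -0.25 for erythroid, -0.66 to -0.41 for early lymphoid, 0.89 to 1.02 for neutrophil, 1.27 to 2.58 for thrombocyte and -0.087 to -0.032 for monocyte genes. They ranged from 0.59 to 1.55 for kidney tubule and epithelium, 2.13 to 2.30 for stroma, 0.065 to 0.63 for endothelium, -0.65 to -0.55 for cell cycle, -0.71 to -0.57 for mitochondrial, 0.37 to 0.59 for quiescence, 1.11 to 1.39 for stress, -0.40 to -0.085 for glycolysis and -0.54 to -0.33 for interferon and MHC genes. They ranged from 0.022 to 0.17 for adhesion, -0.11 to 0.48 for reactive oxygen, -0.15 to -0.034 for housekeeping, -0.74 to -0.67 for ribosomal and -0.60 to -0.30 for proteasome genes.

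After median centring, medians were 0.21 for ABC transporters, -0.18 for Notch, -0.073 for Wnt, 0.061 for monocyte, 2.24 for stroma, 0.069 for housekeeping and -0.60 for ribosomal genes. After a second quantile normalization they were -0.0051 for ABC transporters, -0.13 for Notch, -0.078 for Wnt, -0.083 for monocyte, 2.095 for stroma, 0.42 for quiescence, 0.31 for adhesion, 0.20 for housekeeping and -0.26 for ribosomal genes.

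After cyclic loess, which moved the median of all probe sets from -0.21 to -0.01, medians were 0.20 for ABC transporters, 0.048 for stem cell regulators, -0.086 for Notch, 0.10 for Wnt, 0.29 for TGF-beta and BMP, -0.26 for early lymphoid, -0.13 for erythroid, 1.12 for neutrophil, 0.16 for monocyte and 2.35 for stroma genes. They were -0.34 for cell cycle, 0.76 for quiescence, 1.55 for stress, -0.0006 for glycolysis, -0.11 for interferon and MHC, 0.40 for adhesion, 0.29 for housekeeping, -0.18 for ribosomal, -0.42 for mitochondrial and -0.32 for proteasome genes.

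With the lowest 40% left out, medians were 0.35 for TGF-beta and BMP, -0.80 for erythroid, 0.066 for monocyte, 2.83 for stroma, -0.70 for cell cycle, 0.67 for quiescence, 1.496 for stress and -0.058 for adhesion genes. Above the blank range they were 0.33 for 14 stem cell regulators, 1.65 for 7 TGF-beta and BMP, 5.36 for 8 kidney tubule and epithelium and 3.18 for 9 stroma genes. Some rested on very few members, with -0.076 for 4 Notch, 0.97 for 3 Wnt, -1.99 for 3 T and NK, -1.17 for 3 erythroid and 1.16 for 4 endothelium genes. The B lineage value, 0.72, was that of btk alone. They were -0.99 for cell cycle, 0.70 for quiescence, 1.586 for stress, -0.48 for glycolysis, -0.68 for interferon and MHC and -0.058 for adhesion genes, and no early lymphoid gene was left. With the probe sets of a gene averaged, medians were 0.64 for neutrophil, -0.17 for monocyte, 1.45 for stroma, 0.70 for quiescence and 1.11 for stress genes. Without shared-sequence probe sets they were 2.28 for stroma and 1.12 for stress genes.

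Of the percentiles in the outer 2.5% on either side, those of the ribosomal, proteasome and endothelium lists left it under an alternative. The ribosomal list left it after a second quantile normalization (26.5) and cyclic loess (4.42), the proteasome list without zMP replicate 1 (14.3), without zSP replicate 2 (5.85) and after cyclic loess (2.69). The endothelium list left it without zSP replicate 2 (88.5), without zMP replicate 1 (92.3), with probe sets averaged (97.0), above the blank range (92.8) and with the lowest 40% left out (91.8). Entering it were reactive oxygen without zSP replicate 1 (99.7) and zMP replicate 1 (99.6), T and NK without zSP replicate 2 (2.03), with probe sets averaged (0.76) and above the blank range (0.09), TGF-beta and BMP (99.4) and housekeeping (97.7) above the blank range, erythroid without zMP replicate 2 (1.26) and with the lowest 40% left out (0.55), and adhesion after a second quantile normalization (98.3). Of 102 named genes, 92 were called, and calls ended for 4 after median centring, 8 after cyclic loess, 3 after a second quantile normalization and 5 with probe sets averaged. Without shared-sequence probe sets the call of cav1 ended at 0.50 and hsp70.3 was not measured. Of 19 named genes with several probe sets, 12 had a probe set with another call and 5 a probe set with another sign. Of the results for named genes and counts of list members, 143 stayed within their spread and 11 moved after median centring, 139 and 15 after a second quantile normalization, and 125 and 29 after cyclic loess.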

Other observations

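Other observations

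The gene families in this part were chosen after the table of genes was seen, and so were the tests of background, of sorting stress and of the normalization. The leukocyte test and the comparisons with the leukocyte list were written before their results, but the leukocyte genes themselves were listed after the data were seen. They are therefore not predictions made ahead of these data.

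Keratin genes had a median difference of 1.102 over 15 members, at the 100th percentile of random lists, with 5 called higher in zSP, krt18a.1 at 6.71, krt8 at 4.68, krt15 at 4.04, krt91 at 3.11 and krt18b at 1.52. Without zSP replicate 2 the keratin median was 0.34, at the 96.0th percentile. Of 24 claudins, 6 were called higher in zSP, among them cldn7b at 5.34 (3.46 without shared-sequence probe sets) and the kidney-type cldn8.1 at 2.42, while their median, 0.04, lay at the 93.4th percentile, and at the 99.7th without zSP replicate 1. Both means of cldn8.1 lay within the blank range. Of 14 annexins, 3 were called higher in zSP, anxa2a at 3.64, anxa5b at 2.11 (1.06 and not called with its probe sets averaged) and anxa1a at 1.94, with a median of 0.28 at the 97.9th percentile, which was 87.3 without zSP replicate 1, 89.7 and 95.9 without zMP replicates 1 and 2, 95.1 after a second quantile normalization and 96.9 after cyclic loess. Of 139 solute carriers, 14 were called higher in zSP, led by slc16a9a at 5.40, slc39a3 at 4.84 and slc2a9l1 at 3.75, and slc25a16 at -1.92 was called higher in zMP. Both means of slc25a16 and of col1a2, named next, lay within the blank range. The solute carrier median was 0.01, at the 99.95th percentile. Of 21 collagens, 5 were called higher in zSP, col9a2 at 3.06, col5a2a at 2.83 (1.52 with its probe sets averaged), col6a3 at 2.29, col1a2 at 2.05 (1.22 averaged) and col15a1a at 1.79, with a median of -0.08 at the 77.1th percentile, which was 0.05 after a second quantile normalization and 0.13 after cyclic loess.

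Of 50 translation initiation factor genes, 7 were called higher in zMP, among them eif2b1 at -2.32 with both means within the blank range, eif2s1b at -1.86, eif3m at -1.70 and eif3f at -1.55, and eif5 at 1.53 was called higher in zSP. The eif5 call ended at 1.39 after a second quantile normalization, and cyclic loess ended those of eif3f, eif3ea, eif3ha and eif4a1b at -1.13, -1.07, -1.17 and -0.64, which left 3 called higher in zMP. Without zMP replicate 2, 7 were called higher in each pool. Their median was -0.55 at the 0.97th percentile, and at the 7.99th without zSP replicate 1. The 59 mitochondrial ribosomal protein genes had a median of -0.42 at the 0.65th percentile, and at the 4.05th without zMP replicate 2, with mrpl3 called higher in zSP at 1.74 and mrpl27 higher in zMP at -1.29. Those calls ended at 1.56 after a second quantile normalization and at -1.21 after both median centring and cyclic loess. In all, 5 were called higher in zMP and none higher in zSP after a second quantile normalization, and none higher in zMP after cyclic loess. RNA polymerase subunits (-0.56, 2.58th percentile), chaperonin CCT subunits (-0.94, 5.60th) and Hox genes (-0.31, 35.1th) lay within the middle 95% of random lists with all arrays. The RNA polymerase percentile left it at 1.77, 2.39 and 0.43 without zSP replicates 1 and 2 and zMP replicate 1, 0.72 after a second quantile normalization and 0.77 after cyclic loess, and the CCT percentile at 1.72 without zMP replicate 1. Among them cct3 at -1.44 was called higher in zMP, a call that ended at -1.20 after cyclic loess.

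In the epithelial and stromal lists, 12 of 28 and 10 of 16 members were called higher in zSP. A difference in background between the arrays is argued against, since it would move the blank controls the same way. Their median was -0.38 (-0.94 to 0.13), and 48 of 49 were lower in zSP. Cells of other types in place of blood cells may account for part of the pattern, since the median of 18 leukocyte genes was -0.64, at the 1.93th percentile, though at the 10.9th without zSP replicate 2 and the 3.12th without zSP replicate 1. The leukocyte genes went both ways, from gmfg at -2.02, arhgdig at -1.77 and wasb at -1.50, called higher in zMP, to alox5ap at 1.94, with both means within the blank range, and plcg2 at 1.56, called higher in zSP. Of these 2 only plcg2 was measured above background. Replacement of blood cells would raise it only if the other cells expressed it more strongly, which was not measured. Leukocyte transcripts remained abundant in zSP, with 11.3 against 12.4 in zMP for laptm5 and 8.89 against 9.53 for ptprc. The sort kept only cells of the lymphoid scatter gate, and how many cells of other types pass that gate was not measured. In addition, 1 epithelial and 2 stromal members stand in other lists too. A blood-cell origin of the epithelial and stromal transcripts in the side population was not tested.

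Of 40 immediate early and stress genes, 20 were called higher in zSP and none higher in zMP. A difference in background is argued against for the 29 members with a zMP mean above the blank range, whose median lay at the 100th percentile of matched random lists. Staining and sorting stress that differed between the gates and a response of the cells in the kidney cannot be told apart, since all 4 arrays carry sorted and stained cells and no unsorted sample exists, so that the 20 called members of 40 speak for neither.

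Cell cycle, ribosomal protein and mitochondrial respiration lists had medians under those of random lists. A difference in background is argued against for all 3, but only for the members with a zSP mean above the blank range. These were 13 of the 53 cell cycle, 72 of the 73 ribosomal and 69 of the 86 mitochondrial members. Their medians lay at the 0.18th, 0.02th and 0.00th percentile. A scaling difference left in the deposited values is argued against only for where the cell cycle and mitochondrial lists stand among genes of similar level. Their highest percentiles after cyclic loess or a second quantile normalization were 0.01 and 0.02. A change of scale that depends on level moves the matched random lists too, so the percentiles do not speak to the size of the medians. After cyclic loess these medians were smaller, at -0.34 and -0.42 against -0.57 and -0.59 as deposited, and some calls in both lists ended. The ribosomal list reached 26.5, so that its low median may come from the normalization. Normalization within RMA was not redone and so was not tested. Whether dilution of the blood cells by other cells in zSP accounts for any of the 3 is left undecided. Their medians differed from that of the leukocyte list by 0.066 (-0.57 to 0.53) for cell cycle and -0.035 (-0.73 to 0.41) for ribosomal genes. For mitochondrial genes the difference was 0.048 (-0.60 to 0.50). Each bootstrap interval spans 0, which the rule written before the result counted for dilution. These intervals are wide and could span 0 without dilution too, so that they do not favour it. The medians were not matched on level, and random lists at the ribosomal level had a median of -0.42. How strongly the other cells express the 3 lists was not measured. The leukocyte genes themselves went both ways, with plcg2 and, within the blank range, alox5ap called higher in zSP. A slower growth of the side population itself was not tested.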
